A study of Gallus gallus with 18 samples.

How the data were processed

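RNA from the trachea of chickens was compared on 18 two-colour cDNA arrays. Per the labels, birds received an attenuated Massachusetts-type infectious bronchitis virus (a coronavirus of the chicken airway, here a vaccine strain) and were inoculated again at day 21. Tracheal RNA was taken at 8 time points, days 1, 3, 5, 8, 12, 21, 22 and 24 after the first inoculation. Control birds received sterile water, and their RNA from all ages was mixed into a single control pool. The sample names put the last time point 3 days after the second inoculation, while the design text gives a shorter interval for it; the text below uses day 24. Each of the 9 RNA groups was hybridised in 4 channels, 2 with Cy3 and 2 with Cy5. An array is named here by its Cy3 group and then its Cy5 group, with C for the control pool and T for a day, so that T12-T21 had day 12 on Cy3 and day 21 on Cy5. Slides 1 to 9 form a closed cycle through all 9 groups, and slides 10 to 18 form closed triangles of 3 arrays each. The design text speaks of different RNA samples on the 4 arrays of a time point and the extraction protocol of pooled samples. The p-values therefore measure at most the spread between these RNA samples, which may be partly or wholly technical. The control channels carry a single pool and so hold no spread between birds. Because the control pool mixes ages, a change with the birds' age and a change after inoculation cannot be separated in any comparison with it.

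The values used are log2 ratios of both channels of each array, 15769 rows by 18 arrays, as the authors deposited them in a value table. Per the labels' protocols, RNA was amplified, copied into cDNA and coupled to the dyes; the scanner, background correction and normalization are not given in the sources used here. The log base was read from the values. On 14 arrays, 43 values exceeded 10. On each such array they equal a single maximum close to the log2 of 1e+05 plus a constant of the array, between -0.26 and 0.22. This maximum repeats except on T8-T22, T12-T24, T21-C and T22-T1, which hold 1 such value each. They look like a stand-in for a zero denominator. Column medians lay between -0.21 and 0.08 (C-T1 -0.09, T1-T3 0.03, T3-T5 -0.20, T5-T8 0.06, T8-T12 -0.05, T12-T21 0.01, T21-T22 -0.01, T22-T24 -0.04, T24-C -0.03, C-T5 -0.02, T1-T8 0.01, T3-T12 -0.21, T5-T21 -0.01, T8-T22 -0.05, T12-T24 -0.01, T21-C 0.08, T22-T1 -0.07 and T24-T3 -0.01). Whether the authors normalised for intensity, and which channel is the numerator, stay unknown. The ratios were read as Cy5 over Cy3. All arrays run the same way: each correlated positively across probes with its prediction from the other 17 arrays, with r from 0.112 (T22-T24) to 0.902 (T12-T24). The sums of log ratios round the triangles also varied less than with any array turned. If the true numerator is Cy3, every sign printed here turns and every positive count becomes a negative one, while sizes, totals and p-values stay as they are. For this reason no probe is said to have gone up or down.

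The table identifies rows by spot ID only. No table used here pairs the IDs with genes, and 0 of them matched the gene table of the reference annotation. The 21 gene lists fixed before the data were examined, the rule for named genes, which needs gene symbols, and the planned reading of the direction from interferon-stimulated genes could therefore not be applied. The 160 control spots (4 kinds named after plant sequences and 1 named after chicken genomic DNA) were left out of the tests. The other spots fall by the start of their ID into 11447 C0004, 1798 DT40subNB, 1248 Pat_, 735 Pat-, 378 DKFZ426 and 3 PEN probes. The 4 probes named below for day 12 have the largest signed differences among probes with values on all 18 arrays and none over 10, and this choice, like the mention of the PEN probes, was made after their values were seen.

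Each array was centred on its median, and probes with a value on at least 14 arrays and with all group differences estimable were kept, 15588 in all. A linear model with a coefficient per group and an intercept for the dye effect was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, leaving 9 residual degrees of freedom, to which variance moderation added 5.45. Differences between any of the 9 groups were tested with limma's moderated F, and 12 single differences with its moderated statistic. Each used Benjamini-Hochberg adjustment over the probes and a threshold of 0.05; a probe past it is said to be called. The difference of changes after the second and the first inoculation was tested as a single coefficient of the same model, a test added after the data had been examined. The size of a difference between groups is the root mean square of the log2 differences over probes with the mean squared standard error removed, so that noise of the size the fit estimates gives about 0 (control spots gave 0.43 at day 12 and 0.54 at day 5); its range is given over fits that each leave out 1 array. The collections of probes were compared with limma's camera, at a preset inter-probe correlation of 0.01 and at an estimated one, and with fry, also after the data had been examined. Array data give no read depth: the number of arrays limits the precision, and the median standard error of a difference was between 0.21 and 0.24 on the log2 scale.

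The fit was tested on simulated data for 15588 probes, with 200 probes changed in a single comparison. For day 5 against the control pool it recovered 51.5% of the probes changed by 1 on the log2 scale, 98.5% of those changed by 2 and 5.88% of those changed by 0.5. For day 12 against the control pool these shares were 43.9%, 97.0% and 1.47%, and for day 22 against day 21 47.0%, 98.5% and 0%. False calls made up 2.83%, 6.93% and 4.95% of the calls in these comparisons. The simulation changed far fewer probes than were called at days 5 and 12 in the data. Its noise was independent between probes and equally wide on all arrays. These shares therefore need not hold for the data. Comparisons that share the control pool share its chance values, so their correlation was set beside that of simulated noise and beside the value with the control arrays split between both comparisons. Alternatives covered centring, array scale, the dye term, array weights, the filter on missing values, robust moderation and leaving out each array. Those added after the data had been examined set values over 10 to missing or left out the 4 day 12 arrays. Labels were also reassigned over the 18 arrays in 100 assignments, the real one included.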

Results

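The series followed gene transcription in the chicken trachea after a live attenuated vaccine virus, in order to describe how a local immune response develops after a first and a second inoculation. The 18 arrays compared 9 groups of RNA: a control pool and the trachea at days 1, 3, 5, 8, 12, 21, 22 and 24. Every group was measured in 4 channels. Day 21 was the day of the second inoculation, so that days 22 and 24 followed it. Each array gave between 15721 and 15767 values, and its log2 ratios had a standard deviation between 0.42 (C-T1) and 1.39 (T3-T12). The 4 arrays with day 12 RNA had the widest ratios, with standard deviations from 1.09 to 1.39, against 0.42 to 0.94 on the other arrays. The control spots were also wider on them, with a median absolute deviation of 0.68 (range 0.50 to 0.99) against 0.40 (range 0.25 to 1.14) elsewhere. Probes carry no gene names here, so the comparisons below are of probes and of whole profiles. Signs follow the Cy5 over Cy3 reading, and turning it exchanges the positive and negative counts.

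The first question was how far the tracheal profile moved over the whole course. By limma's moderated F, 10406 of 15588 probes (66.8%) differed between at least some of the 9 groups, and 10930 had an unadjusted p under 0.05. Day 12 was the group farthest from the mean of the groups for 6604 of the called probes (63.5%), where simulated noise gave 11.2%. That noise was equally wide on all arrays and covered all probes, not only called ones. The day 12 arrays were wider, in control spots too, so 11.2% may be too low for day 12. Day 5 came next with 1159 probes (11.1%), followed by day 1 with 826 (7.94%), of which 667 were positive. Days 22 and 24 were the farthest group for 93 and 92 probes. Without the 4 day 12 arrays, 3945 probes were called, and day 5 was then the farthest group for 1339 of them (33.9%) and day 1 for 808 (20.5%).

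**Figure D1:**
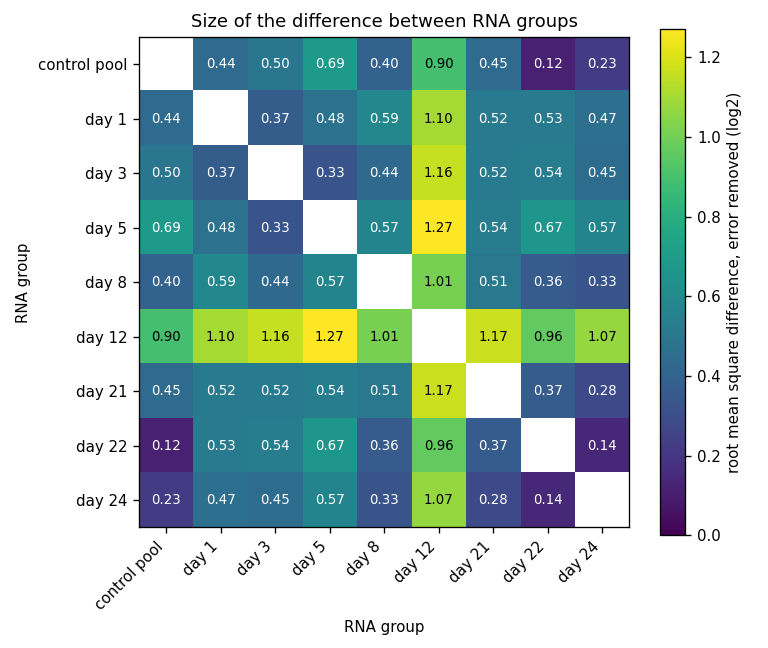
Size of the difference between each pair of RNA groups, as the root mean square log2 difference over probes with the error variance removed (colour and printed value, log2 units). The row of day 12 runs from 0.90 against the control pool to 1.27 against day 5, while the control pool and day 22 lie 0.12 apart.

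From day 1 to day 8 the profile differed from the control pool, at most probes on day 5. The size of the difference was 0.44 at day 1 (0.39 to 0.69 over the fits without 1 array), 0.50 at day 3 (0.46 to 0.62), 0.69 at day 5 (0.60 to 0.77) and 0.40 at day 8 (0.38 to 0.47). At day 1, 1390 probes were called (846 positive, 544 negative), at day 3 1638 (926 and 712), at day 5 4540 (2424 and 2116) and at day 8 766 (304 and 462). The positive share at days 1, 3 and 5 was 60.9%, 56.5% and 53.4%, and with arrays not centred 52.5%, 66.3% and 45.4%, so that the majority at day 5 turned. The difference reached 2-fold for 705, 934, 2104 and 482 of these probes. Day 5 had the largest size of these days in each fit without 1 array, while days 1 and 3 changed places without C-T1 (0.69 and 0.62). Control spots, fitted in the same way, had a size of 0.54 at day 5, so that a size of this order does not by itself separate probes from control spots. The counts depended on single arrays: they were lowest without T22-T1 at day 1 (605), T24-C at day 3 (764), C-T5 at day 5 (1803) and T1-T8 at day 8 (326), and highest without C-T1 on each of these days (2642, 2793, 5213 and 1193).

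Days 1, 3 and 5 were closer to each other than day 12 was to any of them. Days 1 and 3 lay 0.37 apart (0.34 to 0.45), days 3 and 5 0.33 (0.28 to 0.46) and days 1 and 5 0.48 (0.43 to 0.56). Day 12 lay farthest from every group, so this does not make days 1, 3 and 5 a group of their own. Day 1 lay about as far from the control pool (0.44) and from day 24 (0.47) as from day 5. Days 8 and 24 lay 0.33 apart. Across probes, the changes at days 3 and 5 against the control pool correlated with r = 0.819, where noise with the shared pool gave 0.536. With the control arrays split between both changes r was 0.588. The covariance was 0.345 against 0.0411 from noise. Days 1 and 3 gave r = 0.652 (noise 0.547, control arrays split 0.439) and a covariance of 0.193 against 0.0422. Days 5 and 8 gave r = 0.530, no higher than the 0.548 of noise, with a covariance of 0.191 against 0.0423 and r = 0.317 with the control arrays split. Probes are not independent replicates, and no p is attached to these correlations, of which 10 were computed.

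**Figure D2:**
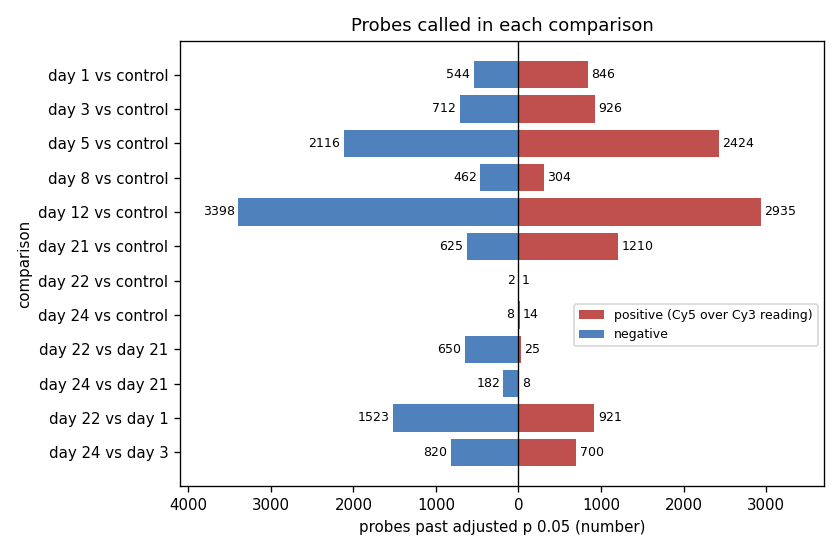
Number of probes past an adjusted p of 0.05 in each of the 12 single comparisons, positive to the right and negative to the left under the Cy5 over Cy3 reading. Day 12 against the control pool has the longest bars (2935 and 3398), days 22 and 24 against it almost none (3 and 22 in all), and day 22 against day 21 lies almost wholly on the negative side (650 of 675).

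Day 12 differed from the control pool at 6333 probes, 2935 positive and 3398 negative, and 3647 of them reached 2-fold. The size of the difference was 0.90 (0.88 to 0.93 over the fits without 1 array), and day 12 lay between 0.90 and 1.27 from each of the other groups; the size in control spots at day 12 was 0.43. Between 5210 and 6604 probes were called when any single array was left out. The probes C0004112_C16 and C0004122_K12 had the largest positive differences, 3.38 ± 0.21 (SE, limma adjusted p 1.7e-07) and 3.14 ± 0.24 (adjusted p 6.89e-07). C0004117_K17 and C0004119_K6 had the largest negative ones, -5.69 ± 0.66 (adjusted p 1.6e-05) and -4.27 ± 0.42 (adjusted p 4.52e-06). All 4 kept their sign on each of the 4 day 12 arrays, with log2 ratios of day 12 over its partner from 2.50 to 3.41 for C0004112_C16 and from -6.34 to -3.41 for C0004117_K17. They were chosen by their difference on these same arrays, so the shared sign is no separate support. The scale of the arrays matters for this comparison: with all arrays brought to the same median absolute deviation, 1307 probes were called and the size was 0.432. This scaling shrinks the day 12 arrays by construction, whatever made them wide. Under that scaling days 1 (0.567; 2476 calls), 5 (0.629; 3557) and 21 (0.449; 1580) had larger sizes and more calls, and day 3 a size of 0.436.

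The change at day 12 correlated negatively with those at days 5 and 21, the days it was set against. Its correlation across probes with the change at day 5 was -0.194, and with that at day 21 -0.278, where noise with the shared control pool gave 0.473 and 0.532. With the control arrays split these were -0.250 and -0.354. The covariances were -0.133 and -0.134 against 0.0367 and 0.0402 from noise.

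Of the 3 probes whose IDs carry a name, PEN_mtd had a negative difference at day 12, -0.77 ± 0.19 (limma adjusted p 0.00453), with the same sign on the 4 arrays; its adjusted p was 0.279 with the arrays scaled. PEN_c-rel gave -0.52 ± 0.21 at day 12 (adjusted p 0.0626; 0.0326 with arrays not centred and 0.0411 without T1-T3) and passed the F test over all groups (adjusted p 0.00299). PEN_TF-10 gave 0.12 ± 0.32 (adjusted p 0.794). No table used here pairs these IDs with genes.

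Day 21, the day of the second inoculation, also differed from the control pool. There were 1835 called probes, 1210 positive and 625 negative, and 802 of them reached 2-fold. The positive share was 65.9%, and it was 56.5% with arrays not centred and 51.3% of 4260 calls with array weights. The size was 0.45 (0.33 to 0.49 over the fits without 1 array). Control spots reached sizes of 0.43 at day 12 and 0.54 at day 5, and their size at day 21 was not computed. This count depended on single arrays: without T21-C, the direct comparison, 42 probes were called, without T5-T21 931 and without C-T5 1207. The changes at days 5 and 21 correlated with r = 0.594 (noise 0.522, control arrays split 0.30), with a covariance of 0.224 against 0.0358.

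After the second inoculation the profile lay close to the control pool. At day 22, 3 probes were called (1 positive, 2 negative) and 1180 had an unadjusted p under 0.05; the size was 0.12 (0.04 to 0.21 over the fits without 1 array). At day 24, 22 probes were called (14 positive, 8 negative) and 2010 had an unadjusted p under 0.05; the size was 0.23 (0.18 to 0.30). Days 22 and 24 lay 0.14 apart (0 to 0.21). The median standard error was 0.235 at day 22 and 0.218 at day 24, against 0.212 at day 21. Without a dye term the sizes were 0 at day 22 and 0.08 at day 24. At day 24 the count moved to 381 without C-T1 and to 2 without T24-C, and to 1704 with array weights.

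Against day 21, day 22 differed at 675 probes, of which 25 were positive and 650 negative, and day 24 at 190 (8 and 182). Under scaled or uncentred values the positive share of these calls stayed between 4.26% and 5.33%, but with array weights it was 10.9% of 1304 calls for day 22 and 30.2% of 1468 for day 24. The sizes were 0.37 (0.31 to 0.50) and 0.28 (0.21 to 0.34). Leaving out T21-C gave 319 and 23 calls, and leaving out T24-C gave 4 calls for day 24. Across probes, the change from day 21 to day 22 correlated with that from the control pool to day 21 with r = -0.805. Noise with the shared day 21 channels gave -0.395, and the covariance was -0.186 against -0.027. Since day 22 lay 0.12 from the control pool, this r largely restates that closeness and is no separate result.

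Days 22 and 1, and by the sample names days 24 and 3, lie equally long after the second and the first inoculation, and their profiles differed. Day 22 differed from day 1 at 2444 probes (921 positive, 1523 negative; size 0.53, 0.43 to 0.61 over the fits without 1 array), and day 24 from day 3 at 1520 (700 and 820; size 0.45, 0.43 to 0.49). Without T22-T1, the direct comparison, 334 probes were called between days 22 and 1, and without T24-T3 402 between days 24 and 3. The positive share of the calls between days 24 and 3 was 46.1%, and 34.1% with arrays not centred.

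The loop allows some differences to be estimated from separate arrays, slides 1 to 9 and slides 10 to 18. Over 15430 probes, both estimates of day 12 minus day 3 correlated with r = 0.858 (Spearman's rho 0.836). Estimated the same way, 5 other differences gave r of 0.567 (day 8 minus day 1), 0.557 (day 22 minus day 1), 0.389 (day 5 minus the control pool), 0.321 (day 24 minus day 3) and 0.314 (day 21 minus the control pool). Further differences within the triangles could have been estimated and were not. These r are across probes of a single pair of estimates. A dye effect shared by the arrays of a part cancels within it, since each part is made of closed cycles.

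**Figure D3:**
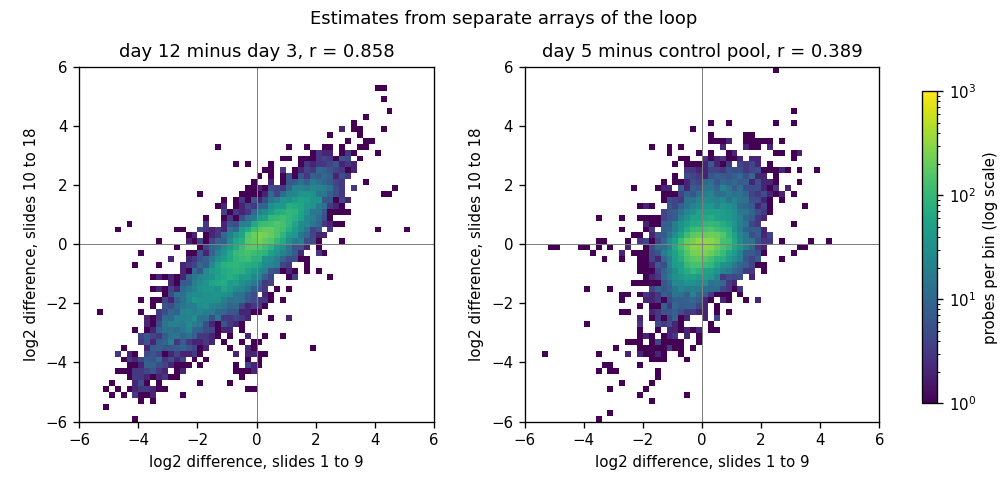
Log2 differences of each probe estimated from slides 1 to 9 (horizontal axis) and from slides 10 to 18 (vertical axis), for day 12 minus day 3 and for day 5 minus the control pool; colour gives the number of probes per bin of 0.2 on a log scale. The cloud follows the diagonal closely for day 12 (r = 0.858) and loosely for day 5 (r = 0.389); 4 and 1 probes lie outside the axes.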

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

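The differences of changes and the tests of the dyes, the printing plates, the parts of the loop and the precision at day 22 were chosen after the result was seen; leaving out single arrays was planned, but its use as a test of day 12 also came after it. The step after the second inoculation was tested against the step after the first. These steps start from unlike groups, day 21 of inoculated birds and a water-treated pool of all ages. A difference between them therefore also holds the offset of day 21 from the pool. The step from day 21 to day 22 differed from that from the control pool to day 1 at 3502 probes (1431 positive, 2071 negative; 5511 at an unadjusted p under 0.05 by limma). Both steps had opposite signs at 93.1% of these probes, and at 63.4% of all probes. The step from day 21 to day 24 differed from that from the control pool to day 3 at 1650 probes (643 positive, 1007 negative; 4188 unadjusted), with opposite signs at 87.2% of them, and at 52.7% of all probes. Probes called for a difference of steps favour opposite signs by selection. Only 59 and 9 probes were called in both steps singly. Across probes the first pair of steps correlated with r = -0.345 (noise 0.249) and the second with r = -0.117 (noise 0.117). Leaving out T21-C reduced the counts to 1334 and 90, and leaving out T22-T1 the first to 1466. The second was 2891 without C-T1, 837 without C-T5, 1022 without T5-T21, 854 without T12-T24 and 461 without T24-T3. Of 100 assignments of the array labels, 1 gave as many probes for the first difference, the real one, with 3546 of the 15431 probes with all values against 4 in the highest other. For the second it was also 1, with 1676 against 68. Reassigning breaks all groups at once, so that the day 12 differences may enter the error of most other assignments (median of the others 0 calls), and chance is not excluded by this for either difference alone.

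Day 12 stood apart from the other groups, with a size of 0.90 against the control pool. The tables argue against a single faulty array, since at least 5210 probes were called without any of the 18, and against a dye effect, since day 12 over its partners correlated with r = 0.750 between the arrays with day 12 on Cy5 and those with it on Cy3. Printing plates accounted for 0.617% of the variance of the change among the C0004 probes. A wider scale of the day 12 arrays stays open and may account for the place of day 12 above the other days. Control spots, named after plant or genomic sequences, spread 1.69 times as widely on these arrays as on the others, though the ranges overlap. The probes spread 2.04 times as widely. With equal scales the size was 0.432 with 1307 calls, below days 1 (0.567), 5 (0.629) and 21 (0.449) and close to day 3 (0.436). Scaling shrinks the day 12 arrays by construction, whatever made them wide, so the scaled values cannot decide between a wider scale and a difference of the RNA. Of 156 control spots, 1 was called at day 12, but they were moderated and adjusted apart from the probes. A property of the day 12 samples other than the response to the virus cannot be told apart from it, since both predict that the parts of the loop resemble each other (r = 0.858 for day 12 minus day 3), and the biological explanation, a response peaking near day 12, is untested since the control RNA was pooled over ages.

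Day 22 lay near the control pool and day 21 did not, although they are a day apart. Lower precision at day 22 as the whole cause is argued against, since the day 21 estimates, with noise added up to the standard errors of day 22, still gave at least 1186 calls in 20 draws; the difference between both sizes, 0.33, was 2.03 times its jackknife standard error of 0.16. The counts cannot decide whether a single array is the cause. T21-C joined day 21 to the control pool directly, while no array joined day 22 to it directly. Without T21-C, 42 probes were called at day 21, against at most 5 at day 22 without any single array. Most of the 1835 calls at day 21 therefore rest on T21-C. The size at day 21 was still 0.33 without T21-C. It exceeded the size at day 22 by at least 0.24 without any single array, so the difference in size does not rest wholly on a single array. Control spots had sizes of 0.43 at day 12 and 0.54 at day 5, and their sizes at days 21 and 22 were not computed. How far the sizes at days 21 and 22 separate probes from control spots is therefore not known. It stays open whether the control pool, which mixes RNA of all ages, lies nearer to day 22 by its make-up, and the biological explanation, an effect of the second inoculation, is untested, since no group holds birds inoculated once at the ages of days 22 and 24, and water-treated birds of those ages are measured only within the pool.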

How the results depend on the processing

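The alternatives were fixed before the data were examined, except values over 10 set to missing and leaving out the 4 day 12 arrays, and the differences of changes were themselves added later. Counts of calls stayed within 1.5 times of the main count for 104 of the values under alternatives and moved further for 45; for left-out arrays these were 194 and 76. None of the counts moved with values on all 18 arrays required, with every probe that could be fitted, with robust moderation or with values over 10 missing. Arrays not centred gave 124 calls for day 24 against day 21. Scaled arrays gave 2476 at day 1, 800 at day 3, 404 at day 8, 1307 at day 12, 1 at day 22 (0% positive against 33.3%), 256 at day 24, 47 for day 24 against day 21, 767 for day 24 against day 3 and 577 for the difference of changes of day 24. The scaling shrinks the day 12 arrays by construction. Without a dye term the counts were 581 (day 1), 748 (day 3), 340 (day 8), 685 (day 21), 1 (day 22), 7 (day 24), 190 (day 22 against 21), 6 (day 24 against 21), 1383 (day 22 against 1), 743 (day 24 against 3), and 1961 and 559 for the differences of changes of days 22 and 24. A dye term for each part of the loop gave 1 at day 22 and 13 at day 24. Array weights, lowest for C-T1 (0.297), gave 2498 (day 1), 1420 (day 8), 4260 (day 21), 5 (day 22), 1704 (day 24), 1304 (day 22 against 21), 1468 (day 24 against 21), 3820 (day 22 against 1), and 5423 and 2501 for the differences of changes. Without the day 12 arrays, which leaves fewer arrays for each estimate, there were 3945 by F, 752 (day 1), 621 (day 3), 311 (day 8), 1009 (day 21), 1 (day 22), 3 (day 24), 350 (day 22 against 21), 0 (day 24 against 21; 1385 at an unadjusted p under 0.05 by limma), 637 (day 24 against 3), and 564 for the difference of changes of day 24. Apart from the scaling and the fewer arrays, the cause was not tested. Leaving out each array gave 605 to 2642 at day 1 (lowest T22-T1, highest C-T1; T1-T3 706, T24-C 689, C-T5 790, T1-T8 840, T21-C 679), 764 to 2793 at day 3 (T24-C, C-T1; C-T5 954, T3-T12 1012, T21-C 811, T24-T3 980), 1803 to 5213 at day 5 (C-T5, C-T1), 326 to 1193 at day 8 (T1-T8, C-T1; T5-T8 347, T8-T12 507, T24-C 384, C-T5 498, T8-T22 447, T21-C 433), 5210 to 6604 at day 12, 42 to 2677 at day 21 (T21-C, C-T1; C-T5 1207, T5-T21 931), 1 to 5 at day 22 and 2 to 381 at day 24 (T24-C, C-T1), where 13 and 14 of the left-out arrays moved the count. It gave 319 to 883 for day 22 against 21 (T21-C lowest; T22-T24 341, T5-T21 432, T8-T22 420, T22-T1 403), 4 to 283 for day 24 against 21 (T24-C lowest; T12-T21 32, T5-T21 74, T8-T22 122, T12-T24 49, T21-C 23, T22-T1 118, T24-T3 61), 334 to 3197 for day 22 against 1 (T22-T1 lowest), 402 to 2267 for day 24 against 3 (T24-T3 lowest; T12-T24 905), and 1334 to 4478 and 90 to 2891 for the differences of changes. By F it gave 9490 to 10791. PEN_TF-10, not called at day 12, ranged from -0.11 to 0.32, with the sign changed to -0.11 without T12-T21, to -0.10 without T24-C and to -0.03 without T12-T24. The 21 gene lists were not run, for want of gene names, and slides 1 to 9 and 10 to 18 alone were used for values and correlations, not for counts. No paired analysis was possible because no pair of groups was hybridised on more than 1 array and the labels number no replicates. The number of arrays limits the precision; signal over background was not used here.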

Other observations

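All tests of the probe collections in this part were chosen after the values had been seen; those with reassigned labels were not. Probes of the DT40subNB collection, whose name contains that of the chicken B-cell lymphoma line DT40, had positive means on all days against the control pool except day 12, and were called at the preset correlation on days 3, 5, 8 and 24. Their mean log2 difference from the control pool was 0.22 at day 3, 0.29 at day 5 and 0.16 at day 8. Of 1796 probes, 240 were called at day 3 (211 positive), 575 at day 5 (446 positive) and 75 at day 8 (60 positive). At day 21 the mean was 0.13 with 224 calls (185 positive; preset adjusted p 0.173), and at day 24 0.13 with no called probe (preset adjusted p 0.0137, estimated 0.547). For days 3, 5 and 8 the limma camera adjusted p with the preset correlation was 0.000375, 0.000555 and 0.000549, and with an estimated correlation the adjusted p was 0.445 on each day, so the shift of the collection against the other probes was not called there. The mean at day 5 lies within the range of the C0004 plate means on that day (-0.23 to 0.46), and plates accounted for 4.72% of the variance among the C0004 probes there; the means at days 3 and 8 lie above the highest plate means (0.16 and 0.09). By fry, which tests the collection alone, the adjusted p was 0.0619, 0.0283 and 0.257. What the clones of this collection are is not stated in the sources used here.

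At day 12 the clone collections had different means, without a call for any of them at an estimated correlation (adjusted p from 0.342 for C0004 to 0.985 for DT40subNB). By fry, which tests each collection alone, the adjusted p was 0.0149 for DKFZ426, 0.0335 for C0004, 0.0619 for Pat_, 0.0904 for Pat- and 0.367 for DT40subNB. The mean difference from the control pool was 0.36 for DKFZ426 (157 of 202 called probes positive), 0.28 for Pat_ (450 of 577) and 0.16 for Pat- (226 of 351), against -0.17 for C0004 (1708 of 4322 positive) and -0.21 for DT40subNB (394 of 880), whose median was -0.02 and whose adjusted p was 0.757 with the preset correlation. At day 21 the first 3 had means of -0.20, -0.20 and -0.15, and C0004 0.06. The lower mean of DKFZ426 and Pat_ (0.278) lies above all 30 plate means of C0004, from -0.36 to -0.02. Plates were read from the IDs and lie within collections, so this cannot decide whether printing plates are the cause. Probes that vary together within a collection stay open as a candidate explanation: at day 12 the lower adjusted p of DKFZ426 and Pat_ with an estimated correlation was 0.445, against 5.2e-05 and 1.83e-05 with the preset one, so it cannot be told apart from a shift of whole collections, and no biological explanation was tested.

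Over all groups, 63.3% of the C0004 probes were called by limma's F, against 78.0% of DKFZ426, 73.9% of DT40subNB, 79.1% of Pat_ and 76.7% of Pat-. Of 156 control spots without values over 10, 3 (1.92%) were called by F. An unadjusted p under 0.05 by F was found for 22 (14.1%). Of these, 11 were PRKase spots, 5 NAC1, 3 Cab, 3 RUBISCO and 0 ChickenGenomic. The share is higher than independent noise would give. The spots are repeats of a few kinds and not independent, so how far it exceeds noise cannot be told. The control spots were moderated and adjusted apart from the probes, so both called shares do not rest on the same cut-off. Their median residual standard deviation was 0.52, against 0.33 for the probes, and their size of change was 0.43 at day 12 and 0.54 at day 5.

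The labels of the 18 arrays were reassigned in 100 assignments, the real one included, over the 15431 probes with all values. For the F test 1 assignment gave as many calls, the real one (10403, highest other 666). The same was seen for day 3 (1 assignment; 1699, highest other 56), day 5 (1; 4538 and 2610), day 12 (1; 6349 and 1086), day 21 (1; 1858 and 3) and day 22 against day 1 (1; 2448 and 2). For day 1, 4 assignments gave as many (1416, highest other 3287), for day 8 2 (797 and 2336), for day 24 2 (22 and 125), for day 22 against day 21 2 (694 and 2747), for day 24 against day 21 3 (191 and 2830) and for day 24 against day 3 2 (1544 and 1716). For the F test, where only the real assignment gave as many calls, chance is argued against for the 9 groups as a whole. For the single comparisons, day 12 included, chance is not excluded by these shares. Reassigning breaks all groups at once, and the day 12 differences may enter the error of most other assignments (median of the others 0 calls). For day 22 against the control pool 5 assignments gave as many (3, highest other 2525), so chance cannot be excluded for its 3 calls. Some assignments called several times the real count, and what these share was not examined.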
